A study of Zea mays with 18 samples.

How the data were processed

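RNA-seq libraries were made from the roots of 10-day-old maize seedlings that had been held for 48 h in nutrient solution with either 0.15 mM or 15 mM nitrate. Per the labels, RNA was extracted with the RNAprep Pure kit and libraries for mRNA were prepared with a Hieff NGS Ultima kit. There were 3 genotypes, 2 nitrate levels and 3 repeats of each, which gave 18 libraries in 6 groups. The labels do not say that the repeats came from separate plantings, so the p-values measure the spread between these samples, which may in part be technical.

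The authors deposited 2 tables of 41632 genes each. The deposited count table held raw, whole-number read counts per gene, and it was the source of all main results. The deposited FPKM table held values normalised by the authors for gene length and library size. The FPKM values were 0 wherever the counts were 0, and in 19280 genes with more than 50 counts in every library the gene length implied by the 2 tables varied between libraries by a coefficient of variation of at most 0.039%. Per the submitters' processing notes, the tools were bcl2fastq 2.19.1, Trim Galore 1.18, HISAT2 2.2.1 and featureCounts 2.0.1 with the genome build B73 RefGen_v4. The order of the steps, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Counts of genes with near-identical copies, of overlapping genes and of antisense genes are therefore uncertain.

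Total counts per library lay between 21905877 and 39003607, and the 10 most abundant genes of a library took 2.06% to 3.20% of them. Of the 41632 genes, 6637 had 0 counts in all 18 libraries. Genes were kept for testing with filterByExpr at its default minimum count of 10 and the 6 groups as its grouping, which left 27134 genes that held 99.97% of the counts. Libraries were scaled by the trimmed mean of M-values (TMM). CPM, the count of a gene relative to the library total, is TMM-scaled throughout. One model with a mean for each of the 6 groups was fitted to all 18 libraries with the quasi-likelihood functions glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, with 12 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the 27134 genes. A gene is called when its adjusted p is under 0.05. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of its F statistic.

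The 9 planned contrasts were the response to nitrate supply in each genotype, low against high nitrate, the difference of each line from B73 at each nitrate level, and the difference of each line's nitrate response from that of B73, tested as an interaction. The difference between the nitrate responses of ZmNRL1-OE and zmnrl1-m was added after the data had been examined. A response index measured how far the nitrate response of a genotype followed that of the genotype left out of the comparison, over the genes called there. For each library it is the mean log2 CPM (prior count 2) of those genes, each multiplied by 1 or -1 for its direction there. The index response is the mean at low nitrate minus the mean at high nitrate. Differences between genotypes were tested with an exact two-sided permutation of the genotype labels within each nitrate level (400 assignments). This permutation is exact only for genotypes that do not differ in the index at either nitrate level. A difference in level between genotypes enters the permuted values, so for equal responses alone the p is approximate.

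Genes are given by the identifiers of the files. The files do not pair these identifiers with names, and 0 of them were found among the 49888 genes of the RefSeq table for the NAM-5.0 assembly that was at hand. The 35 gene lists and the tissue markers fixed beforehand were therefore not tested, and the expression of ZmNRL1 itself, which would check the genotype labels, was not analysed here. The rule for named genes, in its form for identifiers without names, took for each contrast the 2 higher and the 2 lower called genes with the largest fold change, with a mean of at least 5 CPM in at least 1 group compared and, except for interactions, no overlap between the replicates of the 2 groups. Where a group had 0 counts, the fold is given as a bound against a floor of 3 counts over the 3 libraries of the group. Such bounds and the 95% exact binomial intervals of ratios of counts cover counting error only.

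Replicates were compared before use. The 18 pairs of libraries within groups differed by a chi-square of 7.8 to 25.6 per degree of freedom over genes with a summed count of at least 20, so no library was taken for a duplicate of another. Replicate numbers are shared across groups. The deviations from the group means of same-numbered libraries correlated across genes with r = 0.41, 0.12 and 0.26 between the low- and high-nitrate groups of B73, all above the limit of 0.1 that had been set for pairing. In every other contrast of 2 groups at least 1 of the 3 correlations was below 0.1. The labels do not say what a number stands for, so this pairing comes from the data alone. The main model has no block for the number.

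The alternatives were RLE size factors, scaling by library size only, no filter on low counts, a stricter filter (at least 5 CPM in at least 3 libraries), an added limit of a 2-fold change, DESeq2 1.42.0, a fit to the groups compared alone, limma 3.58.1 on log2(FPKM + 1) and on log2(FPKM + 0.1), the replicate number as a block, and leaving out each library in turn. A block within B73 alone, leaving out both B73 libraries with number 1, limma on log2 CPM with and without the leading axis of variation within the ZmNRL1-OE groups, the definition of silent genes, the correlations of the nitrate responses and the count of genes called in all 3 of them were chosen after the data had been examined. The 9 contrasts with their tests, the named-gene rule and the other alternatives were fixed before the data were examined. Several tests of explanations were chosen later and are named as such where they are given.

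The scripts were tested on simulated data: counts were drawn from the real gene means, library sizes and dispersions, with 200 genes changed in the low-nitrate libraries of B73, drawn from genes above 1 CPM in B73 and zmnrl1-m. For the nitrate response of B73, 52.2% of the 67 genes changed by 1.5-fold, 85.1% of the 67 changed by 2-fold and 97.0% of the 66 changed by 4-fold were called by edgeR among 26926 genes tested, with 9 calls among the unchanged genes. For the difference in response between zmnrl1-m and B73 the shares were 25.4%, 65.7% and 93.9%, with 7 calls among the unchanged genes. DESeq2 called 62.7%, 89.6% and 98.5% of the changed genes for the nitrate response of B73 with 42 calls among the unchanged genes, and 41.8%, 79.1% and 97.0% for the difference in response with 44. limma made 14 and 6 calls among the unchanged genes.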

Results

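The root transcriptome was measured in 3 maize genotypes supplied with low (0.15 mM) or high (15 mM) nitrate for 48 h. The genotypes were the inbred line B73, the line zmnrl1-m, taken from its name as a mutant of ZmNRL1, and ZmNRL1-OE, taken from its name as an overexpression line. The series title presents ZmNRL1 as a regulator of the maize response to nitrogen stress, and the design asks how roots of each genotype respond to nitrate supply and whether that response differs from the response of B73. Each of the 6 groups had 3 libraries. The mean total read count at low nitrate was 27665918 ± 7102841 in B73, 32904487 ± 1689141 in zmnrl1-m and 30854001 ± 8005155 in ZmNRL1-OE, and at high nitrate 35372499 ± 3145292, 27380451 ± 5422760 and 35489605 ± 3418746 (SD, n = 3 each). Genes are named by identifier, since the files do not pair identifiers with names.

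Genotype set the largest differences between the libraries, and nitrate supply a smaller one. The first and second principal components of log2 CPM held 50.4% and 30.9% of the variance and separated the 3 genotypes, and the third held 6.54% and separated low from high nitrate in every genotype. Across genes, log2 CPM correlated with r = 0.983 to 0.993 between libraries of a group and with r = 0.966 to 0.984 between the nitrate levels of a genotype. Between genotypes r was 0.870 to 0.887 for B73 and zmnrl1-m, 0.882 to 0.922 for B73 and ZmNRL1-OE, and 0.847 to 0.875 for the 2 lines. Genes are not independent replicates, and these values describe the libraries. All 18 libraries correlated best with a library of their own group.

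**Figure D1:**
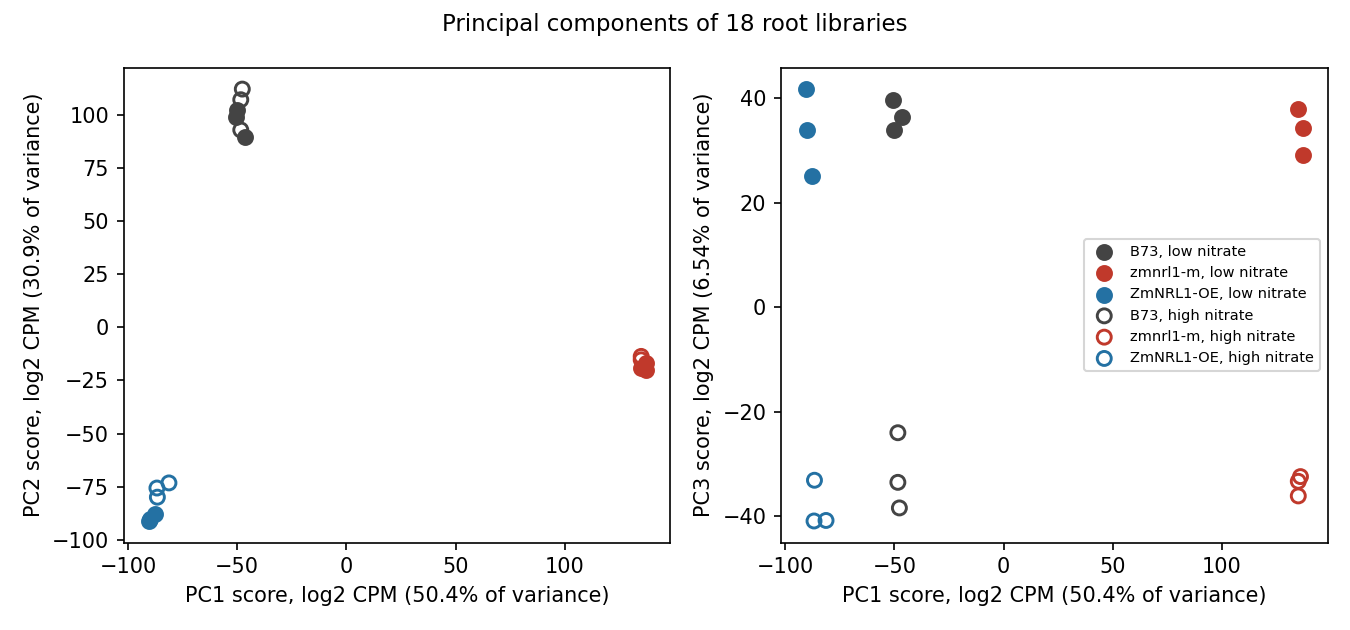
Scores of the 18 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with colour for genotype and filled or open points for low or high nitrate. The genotypes form 3 separate clusters on components 1 and 2, and on component 3 the low-nitrate libraries lie between 25.2 and 41.8 and the high-nitrate libraries between -40.9 and -24.0.

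In roots of B73, low nitrate raised more genes than it lowered. Zm00001d044504 rose 72-fold, from 0.112 ± 0.047 CPM at high nitrate to 8.55 ± 1.88 CPM at low nitrate, and Zm00001d013261 rose 21.6-fold, from 2.23 ± 0.452 to 47.9 ± 3.29 CPM (SD, n = 3). Zm00001d046137 fell 22.9-fold, from 10.4 ± 3.58 to 0.423 ± 0.260 CPM, and Zm00001d043427 fell 22-fold, from 22.6 ± 2.27 to 0.994 ± 0.464 CPM. Their log2 fold changes were 6.17 ± 0.67, 4.43 ± 0.40, -4.52 ± 0.47 and -4.46 ± 0.30 (SE), with edgeR adjusted p of 1.68e-05, 3.27e-06, 1.13e-05 and 9.15e-08. Without low-nitrate replicate 2 of B73 the log2 fold change of Zm00001d046137 was -5.23. Of 27134 genes tested, 3998 were called, 2507 higher and 1491 lower at low nitrate. Changes of at least 2-fold were found in 771 of the higher and 266 of the lower genes. The count was 2341 without low-nitrate replicate 2, 2202 without low-nitrate replicate 3 and 2054 without high-nitrate replicate 2 of B73.

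In zmnrl1-m nearly as many genes rose as fell at low nitrate. Zm00001d026102 rose 40.6-fold, from 0.140 ± 0.0583 to 5.75 ± 2.11 CPM, and Zm00001d011679 rose 23.4-fold, from 2.85 ± 0.962 to 65.9 ± 2.92 CPM (SD, n = 3). Zm00001d009351 fell 49.9-fold, from 324 ± 17.8 to 6.48 ± 1.2 CPM, and Zm00001d023873 fell 39.8-fold, from 5.14 ± 2.26 to 0.122 ± 0.108 CPM. The edgeR adjusted p were 1.54e-06, 5.65e-09, 2.01e-10 and 1.73e-05, with log2 fold changes of 5.35 ± 0.48, 4.55 ± 0.25, -5.64 ± 0.22 and -5.32 ± 0.50 (SE). That of Zm00001d023873 was -6.25 without low-nitrate replicate 3 of zmnrl1-m. In B73, Zm00001d009351 stood at 183 ± 21.6 CPM at high and 9.24 ± 2.35 CPM at low nitrate, and Zm00001d011679 at 3.88 ± 1.07 and 23.6 ± 2.54 CPM. In all, 4846 genes were called, 2413 higher and 2433 lower, with 744 and 669 changed by at least 2-fold. The count was 2970 without low-nitrate replicate 3 and 2915 without high-nitrate replicate 2 of zmnrl1-m.

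ZmNRL1-OE had more called genes in its nitrate response than B73 or zmnrl1-m, while with a 2-fold change required zmnrl1-m had the most (1413, against 1242 in ZmNRL1-OE and 1037 in B73). Zm00001d029776 had the largest rise, 194-fold, from 0.111 ± 0.168 to 20.5 ± 21.8 CPM (SD, n = 3), with a spread at low nitrate as large as its mean. Zm00001d044504, which also led the rise in B73, rose 47.9-fold, from 0.291 ± 0.205 to 14.5 ± 9.68 CPM. Zm00001d045022 fell 29.7-fold, from 65.4 ± 4.8 to 2.15 ± 0.635 CPM, and Zm00001d043427 fell 24.2-fold, from 8.13 ± 1.31 to 0.351 ± 0.154 CPM. Their edgeR adjusted p were 6.8e-05, 7.72e-06, 1.54e-08 and 3.99e-07, with log2 fold changes of 7.60 ± 0.99, 5.58 ± 0.58, -4.89 ± 0.26 and -4.60 ± 0.34 (SE). The size of the rise in Zm00001d029776 rested on single libraries, with a log2 fold change of 6.33 without low-nitrate replicate 3 and 6.98 without high-nitrate replicate 3 of ZmNRL1-OE. It had 11 counts at high nitrate, and without high-nitrate replicate 2 just 1, a ratio of 1620 (95% exact binomial interval 290 to 63900, counting error only; fitted log2 fold change 10.26). Zm00001d044504 had a log2 fold change of 6.38 without high-nitrate replicate 3. The model called 6498 genes, 2943 higher (45.3%) and 3555 lower at low nitrate, with 881 and 361 changed by at least 2-fold. This balance depended on the scaling, since 3424 higher and 2569 lower genes (57.1% higher) were called with library sizes alone, and 3655 and 2631 (58.1%) from log2(FPKM + 1). Leaving out low-nitrate replicate 1, low-nitrate replicate 3, high-nitrate replicate 1 or high-nitrate replicate 3 of ZmNRL1-OE gave 3630, 3251, 3301 or 4093 called genes.

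**Figure D2:**
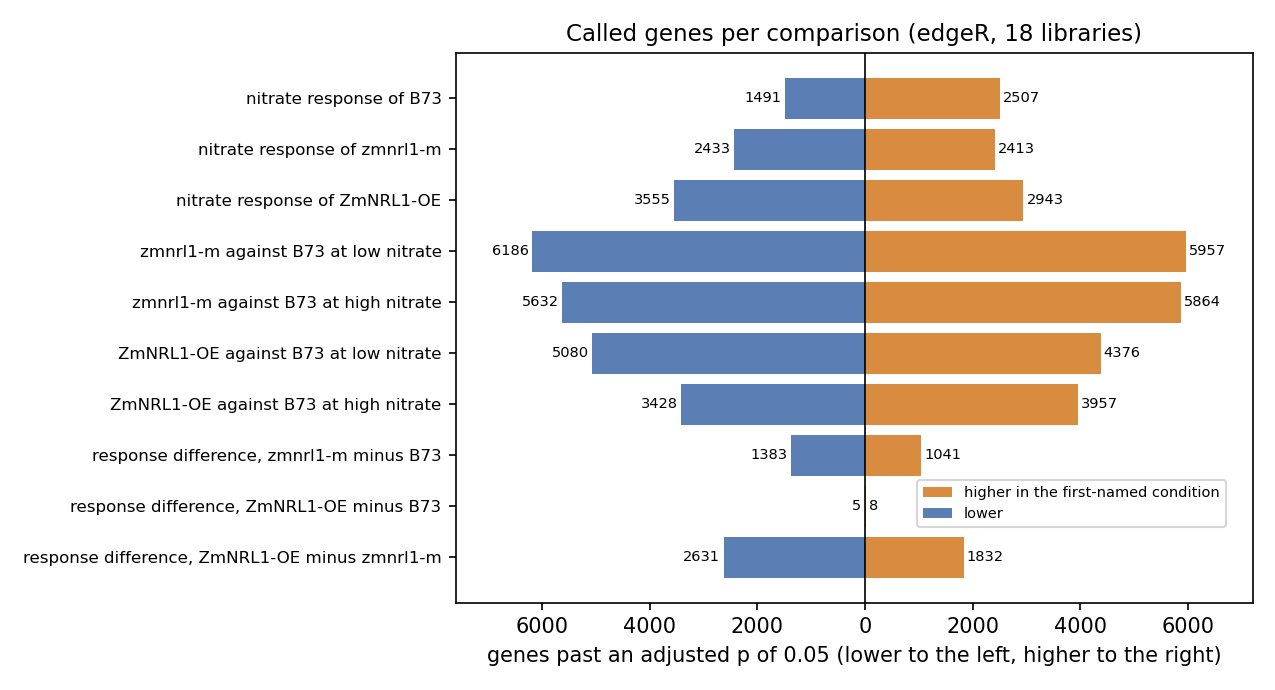
Number of called genes in each comparison (edgeR, adjusted p under 0.05). Genes to the right of 0 were higher at low nitrate or higher in the line than in B73. For differences in response they had the higher signed log2 fold change in the first-named genotype, whatever the size of its response. The lower ones lie to the left. The difference in nitrate response counted 2424 genes between zmnrl1-m and B73 and 13 between ZmNRL1-OE and B73.

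The nitrate responses of the 3 genotypes shared a set of genes that moved in a single direction. At low nitrate 709 genes were higher in all 3 genotypes, where independent calls would give 24.2, and 313 were lower in all 3, where they would give 17.5. Zm00001d013261 was higher at low nitrate in B73, zmnrl1-m and ZmNRL1-OE, with log2 fold changes of 4.43 ± 0.40, 4.67 ± 0.65 and 5.13 ± 0.43 (SE), and Zm00001d044504 with 6.17 ± 0.67, 4.29 ± 0.70 and 5.58 ± 0.58. Zm00001d046137 was lower in all 3, with -4.52 ± 0.47, -5.18 ± 0.51 and -5.18 ± 0.60. Some of these sizes moved with 1 library. Zm00001d013261 gave 4.08 and 5.89 without high-nitrate replicates 2 and 3 of zmnrl1-m, Zm00001d044504 gave 5.22 without high-nitrate replicate 2 of zmnrl1-m, and Zm00001d046137 gave -5.92 without low-nitrate replicate 1 of ZmNRL1-OE, each still called. Zm00001d023873 was also called lower in each, but had 0 counts in the low-nitrate libraries of B73 and ZmNRL1-OE and 0.157 ± 0.0558 and 0.210 ± 0.0635 CPM at high nitrate (SD, n = 3). The median log2 fold change of the 709 genes was 0.96 in B73, 0.91 in zmnrl1-m and 1.05 in ZmNRL1-OE, and that of the 313 genes was -0.89, -1.12 and -0.90.

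The pair of B73 and ZmNRL1-OE had the most genes called in one direction and the fewest called in opposite directions. B73 and ZmNRL1-OE had 1604 genes higher in both (272 for independent calls), 1050 lower in both (195) and 4 with opposite calls (490). B73 and zmnrl1-m had 857 higher in both (223), 421 lower in both (134) and 95 with opposite calls (357). Between zmnrl1-m and ZmNRL1-OE the numbers were 979 (262), 489 (319) and 268 (580). Across the 27134 genes, Spearman's rho of the log2 fold changes was 0.658 for B73 and ZmNRL1-OE, 0.156 for B73 and zmnrl1-m, and 0.117 for zmnrl1-m and ZmNRL1-OE. The low values of rho moved with the processing. For B73 and zmnrl1-m rho was 0.0709 without both B73 libraries with number 1 and ranged from 0.0881 to 0.226 with 1 library left out. For zmnrl1-m and ZmNRL1-OE it was 0.0618 with the stricter filter and 0.0597 to 0.185 with 1 library left out, while for B73 and ZmNRL1-OE that range was 0.580 to 0.662. Pearson's r was 0.557 for B73 and ZmNRL1-OE, 0.358 for B73 and zmnrl1-m and 0.359 for zmnrl1-m and ZmNRL1-OE, and 0.272, 0.175 and 0.174 without the filter on low counts. These are correlations across genes, which are not independent replicates, and no library enters both members of a pair.

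**Figure D3:**
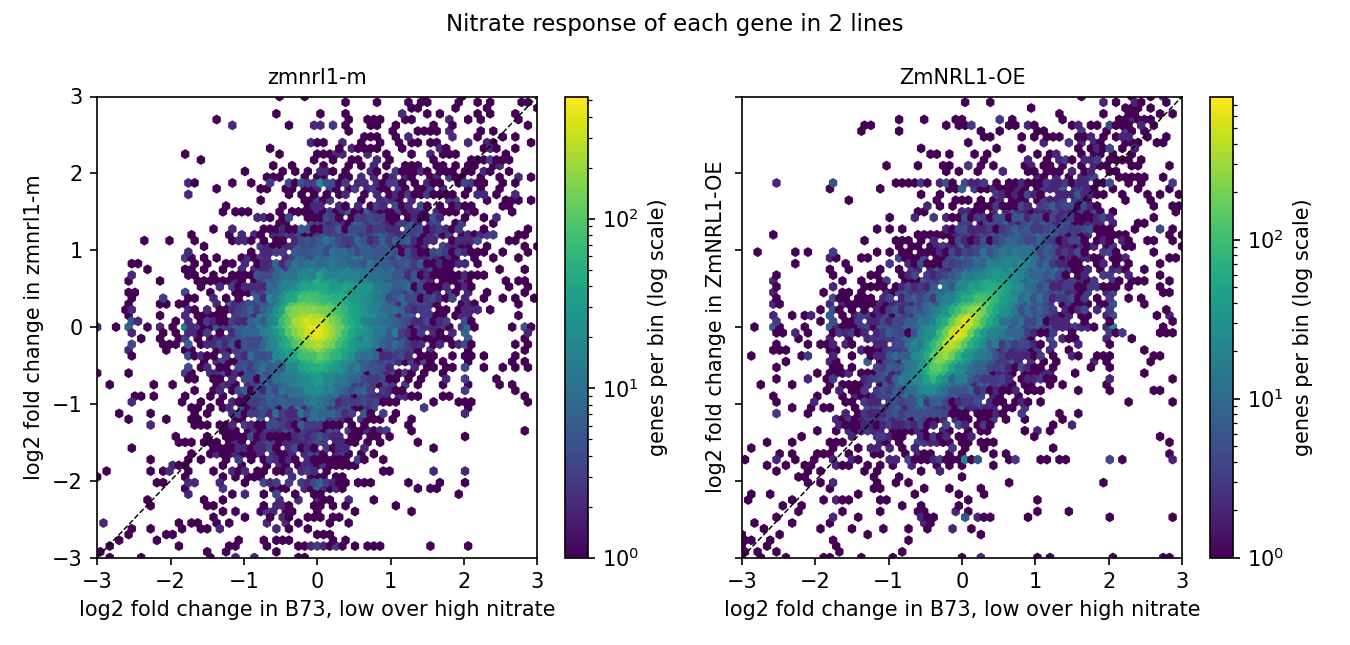
Log2 fold change between low and high nitrate of each tested gene in B73 (x axis) against zmnrl1-m (left) and ZmNRL1-OE (right), as the number of genes per hexagonal bin on a log colour scale. Genes beyond 3 on either axis lie outside the frame, and the dashed line marks equal responses. The responses of ZmNRL1-OE lie along the line (rho = 0.658 over 27134 genes), and those of zmnrl1-m form a rounder cloud (rho = 0.156, and 0.0709 without both B73 libraries with number 1).

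The difference between the nitrate responses of zmnrl1-m and B73 was tested as an interaction. Low nitrate moved Zm00001d048658 from 0.225 ± 0.218 to 2.06 ± 2.56 CPM in B73 and from 6.99 ± 5.07 to 0.582 ± 0.129 CPM in zmnrl1-m (SD, n = 3), a difference in log2 response of -6.61 ± 1.35 (SE). Zm00001d008548 went from 2.74 ± 1.76 to 23.7 ± 27.3 CPM in B73 and from 127 ± 47.9 to 80.8 ± 17.8 CPM in zmnrl1-m, a difference of -3.74 ± 0.87. Zm00001d045391 went from 12.5 ± 7.86 to 4.11 ± 1.41 CPM in B73 and from 0.870 ± 1.08 to 3.48 ± 3.28 CPM in zmnrl1-m, a difference of 3.76 ± 1.06. Zm00001d038870 went from 9.11 ± 2.24 to 7.65 ± 1.37 CPM in B73, and in zmnrl1-m it had 2 counts at high and 52 at low nitrate, a ratio of 21.7 (95% exact binomial interval 5.71 to 184, counting error only). The edgeR adjusted p were 0.0133, 0.0221, 0.0396 and 0.00679 in this order. Zm00001d045391 lost its call in 10 of 23 alternative settings (adjusted p from 0.0249 to 0.149 over all of them), Zm00001d008548 in 3 of 23 (0.00349 to 0.0625) and Zm00001d038870 in 1 of 23 (0.00115 to 0.0611). The sizes also rested on single libraries. Zm00001d048658 differed by -4.85 without low-nitrate replicate 1 of B73, -7.71 without high-nitrate replicate 1 of B73 and -5.90 without high-nitrate replicate 3 of zmnrl1-m, and Zm00001d008548 by -2.21 without low-nitrate replicate 1 of B73. Zm00001d045391 differed by 3.10 without high-nitrate replicate 3 of B73, and by 2.68, 3.13 and 5.45 without low-nitrate replicate 3, high-nitrate replicate 2 and high-nitrate replicate 3 of zmnrl1-m.

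In all, 2424 genes were called for this difference, 1041 with a larger and 1383 with a smaller log2 fold change in zmnrl1-m. In 1923 of them the fitted responses of the 2 genotypes had opposite signs, in 354 both had the same sign and zmnrl1-m had the larger response, and in 147 the smaller one. Choosing genes for a difference favours opposite fitted signs, and 95 of the 2424 were called in opposite directions in the nitrate responses of the 2 genotypes. The nitrate response itself was called in zmnrl1-m but not B73 for 1181 of the genes, in B73 but not zmnrl1-m for 701, in both for 210 and in neither for 332. The count rested on single libraries. It was 546 without low-nitrate replicate 3, 616 without high-nitrate replicate 2 and 899 without high-nitrate replicate 3 of zmnrl1-m, and 744, 685, 706 and 917 without low-nitrate replicates 2 and 3 and high-nitrate replicates 2 and 3 of B73. With the replicate number as a block it was 1569, and DESeq2 called 4150. In simulated data DESeq2 called 44 unchanged genes for this difference and edgeR 7. Leaving out both B73 libraries with number 1, a setting chosen after the data had been examined, gave 3815.

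The nitrate response of ZmNRL1-OE differed from that of B73 in 13 genes, 8 with a larger and 5 with a smaller log2 fold change in ZmNRL1-OE, while 1650 genes had an unadjusted p under 0.05. Zm00001d042828 fell from 6.05 ± 1.35 to 0.896 ± 0.370 CPM at low nitrate in B73 and stood at 0.449 ± 0.0975 and 0.855 ± 0.283 CPM in ZmNRL1-OE (SD, n = 3), a difference in log2 response of 3.71 ± 0.46 (SE). Zm00001d042278 went from 0.630 ± 0.129 to 0.0753 ± 0.0162 CPM in B73 and from 35.0 ± 2.11 to 41.5 ± 1.05 CPM in ZmNRL1-OE, a difference of 3.28 ± 0.35. Zm00001d018737 went from 58.3 ± 9.62 to 63.8 ± 15.3 CPM in B73 and from 84.9 ± 33.8 to 13.6 ± 4.18 CPM in ZmNRL1-OE, a difference of -2.77 ± 0.42. Zm00001d052209 went from 3.89 ± 0.728 to 10.3 ± 2.6 CPM in B73 and from 4.39 ± 0.421 to 2.60 ± 0.541 CPM in ZmNRL1-OE, a difference of -2.14 ± 0.32. The edgeR adjusted p were 0.00347, 0.000866, 0.0184 and 0.0169, and Zm00001d018737 and Zm00001d052209 lost their call in 8 and 3 of 23 alternative settings (adjusted p from 1.48e-07 to 0.0978 and from 7.49e-07 to 0.0716). DESeq2 called 104 genes. Without low-nitrate replicate 3 or high-nitrate replicate 3 of B73 the edgeR count was 8 or 4, and without low-nitrate replicate 2, low-nitrate replicate 3 or high-nitrate replicate 1 of ZmNRL1-OE it was 22, 5 or 7.

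How far each response followed the directions of the response in the genotype left out of a comparison was measured with the response index, over genes called in that genotype. It is not a measure of overall size, and a difference in overall size was not tested. The response of zmnrl1-m had 4846 called genes with a median absolute log2 fold change of 0.64, and that of B73 had 3998 with 0.63. These medians are over genes chosen by the call, and the counts moved with single libraries. Over the 6498 genes called in ZmNRL1-OE, the index response was 0.504 ± 0.060 in B73 and 0.250 ± 0.056 in zmnrl1-m (SE, n = 3 per group). The 2 responses differed by -0.254 on the log2 scale (exact two-sided permutation p = 0.015, where 0.005 is the smallest possible). That p also assumes equal index levels of the 2 genotypes at each nitrate level, so it is approximate for the response alone. The difference was -0.082 over the genes that also changed by at least 2-fold (exact permutation p = 0.555). It was -0.215 as a median over genes (exact permutation p = 0.06), and -0.254 with labels exchanged only between libraries of one replicate number, the blocked test (exact permutation p = 0.0625, 64 assignments). Over the 4846 genes called in zmnrl1-m, the index response was 0.329 ± 0.046 in B73 and 0.336 ± 0.029 in ZmNRL1-OE, a difference of 0.00675 (exact two-sided permutation p = 0.905). The sign of this small difference turned when any of 5 libraries was left out, to values between -0.0194 and -0.00589.

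**Figure D4:**
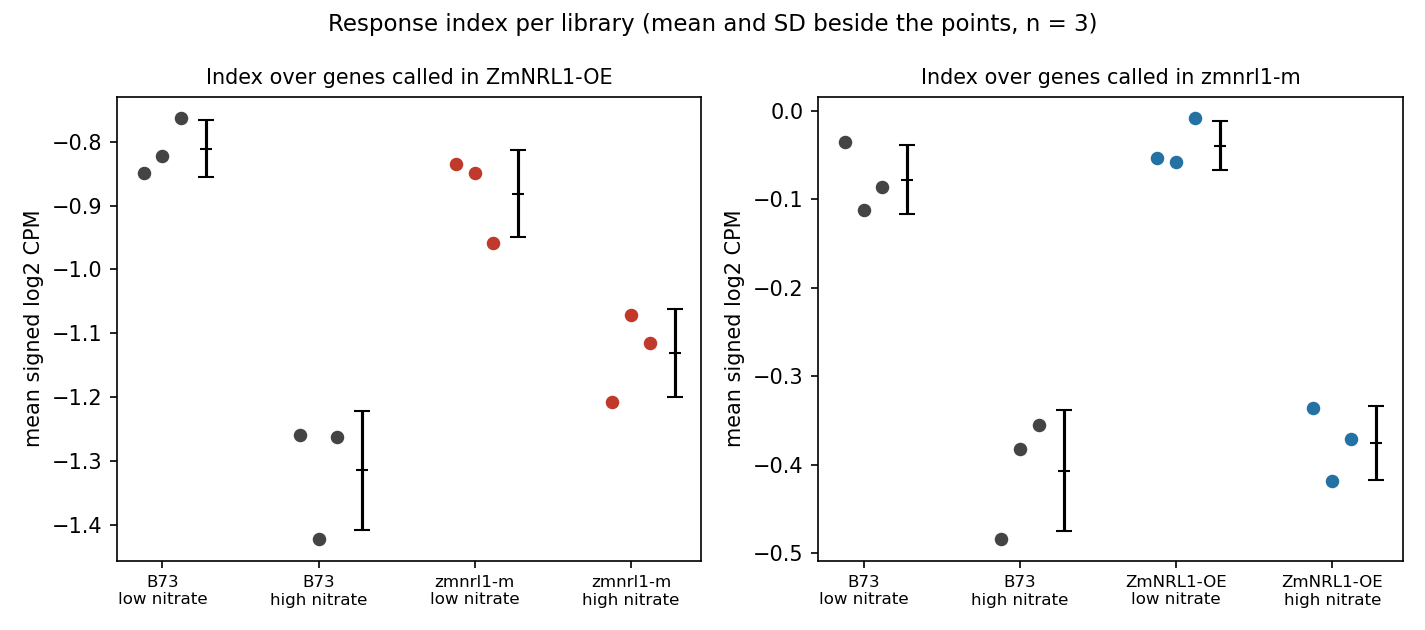
Response index of each library, the mean signed log2 CPM over the 6498 genes called in the nitrate response of ZmNRL1-OE (left) and over the 4846 genes called in that of zmnrl1-m (right). Points are libraries, bars the mean and SD of 3, and the low-to-high step is 0.504 in B73 against 0.250 in zmnrl1-m on the left, and 0.329 against 0.336 in ZmNRL1-OE on the right.

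Roots of zmnrl1-m differed from those of B73 in more than 40% of the tested genes at either nitrate level. The most different genes had many counts in one genotype and few or none in the other, against the B73 genome build. Zm00001d024744 stood at 84.9 ± 6.74 CPM at low and 89.9 ± 5 CPM at high nitrate in B73 (SD, n = 3) and had 0 counts in the 6 libraries of zmnrl1-m, at least 2730-fold and 2390-fold lower. Zm00001d018046 stood at 112 ± 20 CPM in B73 at low nitrate and at 0 counts in zmnrl1-m, at least 3530-fold lower, and Zm00001d008523 at 123 ± 49.0 CPM and 0 counts at high nitrate, at least 3280-fold lower. In the other direction, Zm00001d035590 (113 ± 17.0 CPM) and Zm00001d030287 (25.1 ± 4.67 CPM) in zmnrl1-m at low nitrate had 0 counts in B73, at least 3080-fold and 688-fold higher. At high nitrate Zm00001d049253 (96.2 ± 7.63 CPM) and Zm00001d024014 (41.1 ± 8.32 CPM) were at least 3370-fold and 1470-fold higher. The edgeR adjusted p of these genes lay between 9.81e-13 and 4.13e-08.

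At low nitrate 12143 genes (44.8%) were called between zmnrl1-m and B73, 5957 higher and 6186 lower in zmnrl1-m, with 2253 and 2674 of them apart by at least 2-fold. At high nitrate 11496 genes (42.4%) were called, 5864 higher and 5632 lower, with 2473 and 2249 apart by at least 2-fold. The differences held across nitrate levels, with 3585 genes higher at both (1290 for independent calls), 3518 lower at both (1280) and 211 with opposite calls (2570).

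ZmNRL1-OE also differed from B73, in fewer genes than zmnrl1-m did at either nitrate level. Zm00001d043124 stood at 115 ± 5.18 CPM at low and 85.9 ± 15.6 CPM at high nitrate in ZmNRL1-OE (SD, n = 3) and had 0 counts in all libraries of B73, at least 3180-fold and 2970-fold higher. Zm00001d037149 was at least 1680-fold higher at low nitrate (59.5 ± 9.87 CPM against 0 counts), and Zm00001d004083 at least 1760-fold higher at high nitrate (50.6 ± 6.11 CPM against 0 counts). Zm00001d018704 stood at 300.0 ± 27.2 CPM in B73 at high nitrate and had 0 counts in ZmNRL1-OE, at least 10900-fold lower, and Zm00001d017935 was at least 2720-fold lower (75.0 ± 1.7 CPM against 0 counts). At low nitrate Zm00001d020943 (66.5 ± 11.8 CPM in B73) and Zm00001d041649 (63.7 ± 12.6 CPM) were at 0 counts in ZmNRL1-OE, at least 2110-fold and 2020-fold lower. The edgeR adjusted p of these genes lay between 5.97e-13 and 3.45e-08.

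At low nitrate 9456 genes (34.8%) were called between ZmNRL1-OE and B73, 4376 higher (46.3%) and 5080 lower. With library sizes alone the calls were 5463 higher and 3664 lower (59.9% higher), and from log2(FPKM + 1) 5601 and 3683 (60.3%), so the balance of directions depended on the scaling. At high nitrate 7385 genes (27.2%) were called, 3957 higher (53.6%) and 3428 lower, against 4661 and 2782 (62.6% higher) with library sizes alone and 4544 and 2684 (62.9%) from log2(FPKM + 1). Changes of at least 2-fold numbered 1991 higher and 1468 lower at low nitrate and 1873 and 1286 at high nitrate. Calls at both levels numbered 3066 higher (638 for independent calls), 2786 lower (642) and 5 with opposite directions (1290).

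Whether the mutant and the overexpressor differed from B73 in opposite directions was asked by comparing their calls. At low nitrate 1290 genes were called in both lines with opposite directions, 641 of them lower in zmnrl1-m and higher in ZmNRL1-OE and 649 the reverse, where independent calls would give 2110. In the same direction 3305 genes were called, 1723 higher and 1582 lower in both lines, where independent calls would give 2120. At high nitrate 628 genes went in opposite directions (1560 for independent calls) and 3395 in the same direction (1570). Both lines were compared with the same 3 B73 libraries. In 10 edgeR simulations per nitrate level of groups unchanged from B73, at most 1 gene was called in either line and 0 in both. With so few calls these counts cannot show what the shared libraries add to the real ones. The 3 control libraries are too few to be split, so part of the excess of same-direction calls may come from the shared libraries. The log2 fold changes of the 2 lines correlated across genes with Pearson's r = 0.332 at low and 0.350 at high nitrate, and simulated unchanged groups gave 0.514 and 0.497. Spearman's rho was 0.181 at low and 0.353 at high nitrate, so by rank the 2 lines were less alike at low nitrate. The observed covariances were 0.967 and 1.01, and the simulated ones 0.031 and 0.030. Their differences, 0.936 and 0.980, estimate the part beyond the replicate spread of the shared libraries. A shift common to the 3 B73 libraries would stay in these differences. The number of opposite calls at low nitrate was 802, 850 or 857 without low-nitrate replicate 2 or 3 of B73 or replicate 3 of ZmNRL1-OE, and same-direction calls outnumbered opposite ones each time (2475, 3075 and 2801).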

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

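The tests of same-direction against opposite calls, of the scaling and of the size classes in the nitrate response were chosen after the results they bear on had been seen, and the comparison of ZmNRL1-OE with zmnrl1-m was added after the data had been examined. After results had been seen, the axis of variation tested was narrowed in wording to that of the ZmNRL1-OE groups, and tests of silent genes against depth and against the difference in response were dropped because they were void.

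The nitrate response differed between genotypes by a test of the difference itself. It differed in 2424 genes between zmnrl1-m and B73, in 13 between ZmNRL1-OE and B73, and in 4463 between ZmNRL1-OE and zmnrl1-m. Of the 4463 genes, 1832 had a larger and 2631 a smaller log2 fold change in ZmNRL1-OE, but this balance turned with the processing, to 2160 and 1927 with library sizes alone, 2464 and 2066 from log2(FPKM + 1), 2168 and 1928 from log2(FPKM + 0.1), and 2534 and 2208 with the stricter filter. The index response of zmnrl1-m differed from that of B73 by -0.254 (exact permutation p = 0.015, and 0.0625 in the blocked test). It differed by -0.215 as a median over genes (exact permutation p = 0.06) and by -0.082 over genes changed by at least 2-fold (exact permutation p = 0.555). Among the named genes the log2 response of zmnrl1-m differed from that of B73 by 4.49 for Zm00001d038870, 3.76 for Zm00001d045391, -6.61 for Zm00001d048658 and -3.74 for Zm00001d008548. The log2 response of ZmNRL1-OE differed from that of B73 by 3.71 for Zm00001d042828, 3.28 for Zm00001d042278, -2.77 for Zm00001d018737 and -2.14 for Zm00001d052209.

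The first pattern is the number of genes called between each line and B73. Opposite effects of loss and gain of ZmNRL1 as the whole cause would give more opposite than same-direction calls. Same-direction calls outnumbered opposite calls 2.56 to 1 at low and 5.41 to 1 at high nitrate, which argues against it. This does not exclude it, since the shared B73 libraries may add same-direction calls and the expression of ZmNRL1 was not analysed. A difference in descent between the lines may contribute. The genes at least 4-fold apart from B73 at both nitrate levels were gathered in neighbouring rows of the count table. Their variance between windows of 100 rows was 3.31 times that of shuffled genes for zmnrl1-m (2104 genes) and 3.21 times for ZmNRL1-OE (1452 genes). For the nitrate-responsive genes of B73 it was 1.27 times (3998 genes), and 0.944 times for those changed by at least 4-fold (249 genes). The sets differ in size, which can move the ratio, so these values are not directly comparable. Gene families in neighbouring rows, the order of rows as a stand-in for position, and effects of ZmNRL1 itself remain open, and no label gives the descent of the lines.

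The second pattern is the count of 2424 genes for the difference in nitrate response between zmnrl1-m and B73. The choice among the scalings tried was not its source, since RLE size factors gave 2372 genes and library sizes alone 2254. The FPKM fits, which scale by library size again, gave 2373 with pseudocount 1 and 2205 with 0.1. All of these use a single factor per library. Removing the leading axis of variation within the ZmNRL1-OE groups from the libraries and their group means left 131% of the limma calls (2574 before, 3376 after and 2548 in both). The calls therefore did not rest on this axis alone. It was a weak candidate, since about their group means B73 and zmnrl1-m libraries scored -6.44 to 5.22 on it, against -24.5 to 39.7 in ZmNRL1-OE. Its removal also lowers the spread shared by all groups, which by itself raises calls. The test does not bear on other variation between samples. Leaving out a single library gave between 546 (without low-nitrate replicate 3 of zmnrl1-m) and 3314 (without low-nitrate replicate 1 of B73), and 616, 899, 744, 685, 706 and 917 for the other libraries that moved it, as given in the report. Other axes of variation between root samples remain open. A harvest time or batch shared by B73 and ZmNRL1-OE at each nitrate level but not by zmnrl1-m is also open. So is a difference in descent between zmnrl1-m and B73. The labels give none of these. For the 2424 genes the variance between windows of 100 rows was 1.1 times that of shuffled genes. This ratio cannot decide on descent, since a response altered by descent need not lie in neighbouring rows. These causes stand beside an effect of the mutation.

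The third pattern is the smaller index response of zmnrl1-m along the directions of the ZmNRL1-OE response. Over the 1242 genes that changed by at least 2-fold in ZmNRL1-OE, the response was 1.11 ± 0.074 in B73 and 1.02 ± 0.044 in zmnrl1-m (SE, n = 3 per group), a ratio of 0.926. Over the 5256 genes with smaller changes it was 0.362 ± 0.061 and 0.0671 ± 0.060, a ratio of 0.186. This shortfall, which was measured along those directions and not as overall response size, may lie in the genes with modest changes. The difference of the ratios had an exact permutation p of 0.16. That p assumes genotypes with equal levels and responses in both classes, so for equal ratios alone it is approximate. It does not tell the 2 classes apart on this point with 3 libraries per group. The biological difference that the design names, the genotype at ZmNRL1, remains open as well, as does a difference in descent between zmnrl1-m and B73.

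In fits to the 12 libraries of 2 genotypes, other assignments of the genotype labels within each nitrate level were drawn 100 times, the real one included. For zmnrl1-m and B73 the real assignment gave 2046 genes and 4 of the 100 gave as many, the highest other one 13508, a share under 5%, while 3 of the first 50 drawn, over 5%, had done so. For ZmNRL1-OE and B73 the real assignment gave 6 genes, 3 of the 100 gave as many and the highest other gave 11863, a share under 5%. For ZmNRL1-OE and zmnrl1-m the real assignment gave 3866 genes, 7 of the 100 gave as many and the highest other gave 15999, a share over 5%. These shares do not settle whether chance can be excluded. The large counts point to a structure of the samples: an assignment that exchanges more libraries at one nitrate level than at the other carries the difference between the genotypes into the contrast. Among the 29 assignments with equal exchange at both levels, the real one included, the highest other counts were 0, 1 and 0, but these mix genotypes within groups, which raises the spread and lowers the counts.

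For the 7 contrasts of 2 groups the 6 libraries make 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each. The real values were 3507 for the nitrate response of B73, 3935 for zmnrl1-m and 4998 for ZmNRL1-OE, 10531 and 10381 for zmnrl1-m against B73 at low and high nitrate, and 7879 and 6282 for ZmNRL1-OE against B73, with 0 genes as the highest other value in each. For the nitrate response of B73 this includes the splits that, like the real one, part every same-numbered pair, and the others differ by keeping pairs together.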

How the results depend on the processing

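The block within B73, the removal of both B73 libraries with number 1, the limma fits on log2 CPM and all settings for the comparison of ZmNRL1-OE with zmnrl1-m, for silent genes, for correlations and for genes called in all 3 nitrate responses were chosen after the data had been examined. No called gene was called in the opposite direction in any alternative fit of the 10 contrasts. Changes of sign without a call were not counted. Over the alternatives other than the 2-fold limit and single libraries left out, called genes numbered 3352 to 5123 for the nitrate response of B73, 3935 to 5640 for zmnrl1-m and 4998 to 7270 for ZmNRL1-OE. They numbered 9288 to 12454 and 8670 to 11907 for zmnrl1-m against B73 at low and high nitrate, and 7048 to 9725 and 5486 to 7897 for ZmNRL1-OE against B73. The ranges for a line against B73 leave out the block within B73, which sets B73 at the level of its number-1 libraries. For the response of ZmNRL1-OE against zmnrl1-m the range was 3525 to 6007. Of 641 alternative values of named genes, 616 kept direction and call, 25 kept the direction and lost the call, and 0 reversed.

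Asking for a 2-fold change as well left 1037, 1413 and 1242 genes in the nitrate responses of B73, zmnrl1-m and ZmNRL1-OE, 4927 and 4722 between zmnrl1-m and B73 at low and high nitrate, and 3459 and 3159 between ZmNRL1-OE and B73. It left 752 genes for the difference in response between zmnrl1-m and B73, 1061 for that between ZmNRL1-OE and zmnrl1-m, and 245 and 215 opposite calls at low and high nitrate, by its construction. For zmnrl1-m against B73 in response, DESeq2 gave 4150 genes, and both number-1 libraries of B73 left out gave 3815. For ZmNRL1-OE against B73 in response, no filter gave 20 genes, DESeq2 104, the compared groups alone 6, FPKM with pseudocount 1 gave 41 and with 0.1 gave 24. The index difference of zmnrl1-m was -0.082 over genes changed by 2-fold (exact permutation p = 0.555) and -0.215 as a median (exact permutation p = 0.06). Apart from the 2-fold limit, the cause was not tested. Gene set tests were not run, since the lists could not be matched. Spearman's rho was 0.0618 for zmnrl1-m and ZmNRL1-OE with the stricter filter, and 0.0709 for B73 and zmnrl1-m without both number-1 libraries of B73. Genes called in 1 direction in all 3 nitrate responses numbered 809 to 1185 over the alternatives and 825 to 1065 with single libraries left out.
With the replicate number as a block the difference in response between zmnrl1-m and B73 counted 1569 genes, and its index difference of -0.254 had an exact permutation p of 0.0625. The block changed no other call by over 1.5 times. It gave 3352 genes for the nitrate response of B73, 4324 for that of zmnrl1-m and 5795 for that of ZmNRL1-OE. It gave 11612 and 11009 for zmnrl1-m against B73, 8871 and 6907 for ZmNRL1-OE against B73, and 14 for the response of ZmNRL1-OE against B73. A block within B73 alone gave 3841 genes for the nitrate response of B73 and 2003 for the difference in response between zmnrl1-m and B73. Libraries correlated best with their own number in 5 of 6 cases between the B73 groups, in 3 of 6 between the zmnrl1-m groups and in 0 of 6 between the ZmNRL1-OE groups.

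Leaving out single libraries gave 2054 to 4278 genes for the nitrate response of B73, 2915 to 4439 for zmnrl1-m and 3251 to 7173 for ZmNRL1-OE. It gave 546 to 3314 for the difference between zmnrl1-m and B73, 4 to 22 for ZmNRL1-OE and B73, and 1685 to 5567 for ZmNRL1-OE and zmnrl1-m. The libraries that moved the last count by over 1.5 times were low-nitrate replicates 1 (2374) and 3 (1942) and high-nitrate replicates 1 (1685) and 3 (2510) of ZmNRL1-OE, and low-nitrate replicate 3 (1765) and high-nitrate replicates 2 (1777) and 3 (2547) of zmnrl1-m. Opposite calls at low nitrate ranged from 802 to 1393. The index difference of zmnrl1-m ranged from -0.292 to -0.200 (exact permutation p from 0.01 to 0.045), and that of ZmNRL1-OE from -0.0194 to 0.0455, reversed at -0.0104, -0.0092, -0.00589, -0.0194 and -0.015. Fewer libraries also leave fewer degrees of freedom. With 21905877 counts or more per library, depth limited genes with few counts, as in the 2 counts behind Zm00001d038870.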

Other observations

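The definition of silent genes and the comparison of their overlap were chosen after the data had been examined. Beyond differences in level, each pair of genotypes had genes that were expressed in one and silent in the other at both nitrate levels. Reads were counted against the B73 genome build, so silent describes the counts only. It does not tell an unexpressed gene from one that is missing or altered in a line. With at least 1 CPM in all 6 libraries as expressed and at most 3 counts over 6 libraries as silent, 149 of the 22046 genes expressed in B73 were silent in zmnrl1-m and 83 were silent in ZmNRL1-OE. In the other direction, 151 genes expressed in zmnrl1-m and 145 expressed in ZmNRL1-OE were silent in B73. The median level where expressed was 7.61 CPM for the genes silent in zmnrl1-m and 7 CPM for those silent in ZmNRL1-OE. Genes silent in B73 had lower medians, 3.57 CPM where expressed in zmnrl1-m and 3.96 CPM where expressed in ZmNRL1-OE.

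Genes silent in both lines and expressed in B73 numbered 25, where independent sets would give 0.561, and 28 genes were silent in B73 and expressed in both lines. Another 105 genes were silent in zmnrl1-m and expressed in both B73 and ZmNRL1-OE, and 28 were silent in ZmNRL1-OE and expressed in both B73 and zmnrl1-m. Between the lines, 214 genes were silent in zmnrl1-m and expressed in ZmNRL1-OE, and 146 the reverse. With a limit of 5 CPM for expressed genes, 83 genes expressed in B73 were silent in zmnrl1-m and 45 in ZmNRL1-OE, while 44 expressed in zmnrl1-m and 49 expressed in ZmNRL1-OE were silent in B73, so the near-equal 149 and 151 became 83 and 44. Between the lines 94 genes were then silent in zmnrl1-m and 42 in ZmNRL1-OE. With at most 10 counts for silent genes, 202 genes expressed in B73 were silent in zmnrl1-m and 128 in ZmNRL1-OE, and 212 expressed in zmnrl1-m and 184 expressed in ZmNRL1-OE were silent in B73.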
